A study of Homo sapiens with 4 samples.

How the data were processed

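RNA sequencing of C666-1R cells was analysed from 4 libraries, 2 with a control short hairpin RNA and 2 with a hairpin against HOTAIRM1. Per the labels' protocols, total RNA was made into libraries with the NEBNext Ultra RNA kit and sequenced on a NovaSeq 6000. Per the submitters' processing notes, bcl2fastq 2.20, fastp 0.22.0, HISAT2 2.2.1 and genome build hg38 were used. The program that computed the FPKM values, its transcript annotation and its use of strand are not given in the sources used here.

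The deposited table holds FPKM (fragments scaled to transcript length and to the fragment total of the library), as its name says, with 1 value for each of 76912 Ensembl transcripts in each library. The unit was taken from that name and from values that are decimals with unequal column sums. The fragment totals used as the divisor are not stated, and the low values showed no steps from which whole reads could be recovered, so depth per library is unknown and no count test was run. Every row reached at least 0.100007 FPKM in at least 1 library, and 30.4% of rows had a 0 in at least 1 library. The columns of the control libraries carry the control name and number of the labels. The columns of the knockdown libraries carry a code that the labels do not use, and were assigned to the HOTAIRM1 hairpin because the series has 2 groups and the control name marks the other, with the number taken from the column's ending. Values and column order played no part, and the assignment rests on that elimination.

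Transcripts were matched by identifier to GENCODE 29 on GRCh38 with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Of the rows, 73602 matched and 3310, with 4.15% to 4.46% of FPKM per library, did not and were left out. FPKM was summed per gene over all matched transcripts, which gave 13299 genes, and reads of overlapping or antisense genes, near-identical paralogs and readthrough genes may have been shared or divided by the authors' quantification. Positions are those of the annotation. HOTAIRM1 was not analysed here, so the knockdown could not be checked.

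Genes with a mean of at least 1 FPKM over the 4 libraries, 10956 in all, were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 1.94. The criterion in the series' design text, an unadjusted p under 0.05 and a log2 fold change above 1 or below -1, was applied to the same fit, since its own test is not stated there. Gene lists, 45 in all and 10 of them for cell types, were tested with camera at a preset correlation of 0.01, with camera's estimated correlation and with fry, where at least 3 members passed the filter. That left 39 lists, and adjustment was over those 39, not over all 45 as had been planned. Counts of list members are given over all genes tested and adjusted over the list alone.

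The groups, the main test, the lists, the alternatives below and the rule for named genes were fixed before the data were examined, except where stated. The plan had assumed values per gene. Summing FPKM over all transcript types was therefore settled once the deposited values were found to be per transcript. The rule names HOTAIRM1, SLC7A11 and METTL3, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap (leaving out clone and locus names), and up to 4 members with the smallest p of each list that passed camera or had at least 2 called members, and of both ferroptosis lists, both m6A lists and the HOXA cluster. All members are named where 5 or fewer were measured. A few genes that the rule takes are not reported here, though the counts of their lists include them. A few members that went against their list are named outside the rule, which is said beside them, as are the highest members of the cell type lists.

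The alternatives were pseudocounts of 0.1 and 1, no filter on low values and filters of 0.1 and 5 FPKM, rescaling to the same FPKM total, trimmed-mean factors (30% of log ratios and 5% of mean levels trimmed at each end), quantile normalization, no variance trend, robust eBayes, the replicate number as a block, leaving out each library, a log2 fold change above 1 or below -1 added to the threshold, an adjusted p under 0.1, and the other list tests. Sums over protein-coding transcripts and tests of single transcripts were added after the data were seen. Their effects are given in the closing section.

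The fit was tested on simulated values, 10 runs each. Means were those of the control libraries, and errors were normal. Each gene's spread was drawn from the prior that limma fitted to the real data, limited at its 99th percentile. These values follow the model that the test assumes, so false calls from departures from that model were not tested. With 200 of 10766 genes changed, it called 40.1% of those changed 2-fold, 81.2% of those changed 4-fold and 92.8% of those changed 8-fold in the right direction, with a mean of 9.8 unchanged genes among 148.4 calls (728.8 genes at an unadjusted p under 0.05). With 4000 of 10704 genes changed, where 4091 genes had an unadjusted p under 0.05 against 4096 in the real data, it called 87.0%, 96.7% and 98.85% of those changed 2-fold, 4-fold and 8-fold, with a mean of 128 unchanged genes among 3768 calls. Each simulated change was 2-fold or more. In the real data limma called 1795 genes, and only 408 of these had a log2 fold change above 1 or below -1. The simulated rates therefore do not carry over to the real calls. With 0 genes changed it made 0 calls (a mean of 550.7 at an unadjusted p under 0.05). Camera called a list of 30 genes shifted by 0.5 on the log2 scale in 100% of runs and 0 unshifted lists, and with an estimated correlation it called the shifted list in 0% of runs. The simulated genes were drawn independently of each other. False calls of lists whose members vary together were therefore not tested. Figures were drawn with matplotlib 3.10.9.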

Results

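RNA was sequenced from C666-1R cells, which the series describes as nasopharyngeal carcinoma cells studied for resistance to irradiation, after expression of either a control short hairpin RNA or a hairpin against HOTAIRM1. HOTAIRM1 is a long noncoding RNA transcribed from the HOXA cluster. Each group held 2 libraries, called control 1 and 2 and knockdown 1 and 2. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The knockdown columns carry a code that the labels do not use and were assigned by elimination, since the control columns carry the control name. The deposited FPKM values covered 76912 transcripts, of which those matched to the annotation were summed to 13299 genes. FPKM summed to 355198.8 and 358455.0 in control 1 and 2 and to 363229.5 and 364955.4 in knockdown 1 and 2, with 10873 to 10892 genes at 1 FPKM or more. The read depth is unknown, so no counting error can be given. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.977 between the controls, 0.970 between the knockdown libraries and 0.940 to 0.941 between libraries of different groups. Levels below are group means in FPKM ± SD (n = 2 libraries per group), and fold changes are knockdown over control on the log2(FPKM + 0.5) scale, which understates the change of low genes. HOTAIRM1 itself (ENSG00000233429, chromosome 7, 27095647 to 27100265, plus strand, GRCh38) was not analysed here, so depletion of the target was not checked.

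The series title names SLC7A11, the transporter subunit that imports cystine for glutathione synthesis, and METTL3, the catalytic subunit of the m6A RNA methyltransferase, and the first comparison asked whether their transcripts differed between the groups. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand) was 2.51-fold lower after HOTAIRM1 shRNA, at 22.5 ± 2.84 against 57.0 ± 2.62 FPKM (log2 fold change -1.33, SE 0.11, limma adjusted p = 0.0195). Its value came from a single coding transcript, and 865 of its 9645 exon bases lie opposite the antisense gene SLC7A11-AS1. When rows were tested singly this transcript had limma adjusted p = 0.104. With the replicate number as a block SLC7A11 had limma adjusted p = 0.0796. METTL3 (ENSG00000165819, chromosome 14, 21498133 to 21511375, minus strand) summed to 24.9 ± 5.0 FPKM in control and 25.2 ± 4.35 in knockdown libraries (log2 fold change 0.02, SE 0.20, limma adjusted p = 0.951). Within METTL3, the main coding transcript METTL3-201 stood at 12.4 ± 0.596 in control and 5.71 ± 0.965 FPKM in knockdown libraries, and the retained-intron transcript METTL3-212 at 3.36 ± 0.351 and 13.9 ± 4.87 FPKM. Neither transcript passed the test when rows were tested singly (limma adjusted p = 0.173 for each). METTL3-212 shares 337 exon bases with the neighbouring gene TOX4 on the opposite strand, and the kit's strand use is not stated. Most of those bases lie in METTL3-201 as well. With the coding transcripts alone summed, an alternative chosen after the data were seen, the METTL3 log2 fold change was -1.21 with limma adjusted p = 0.0461, against 0.173 to 0.997 under the other alternatives. Without any 1 of the 4 libraries the SLC7A11 log2 fold change lay between -1.45 and -1.20 and its limma adjusted p between 0.0974 and 0.128.

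**Figure D1:**
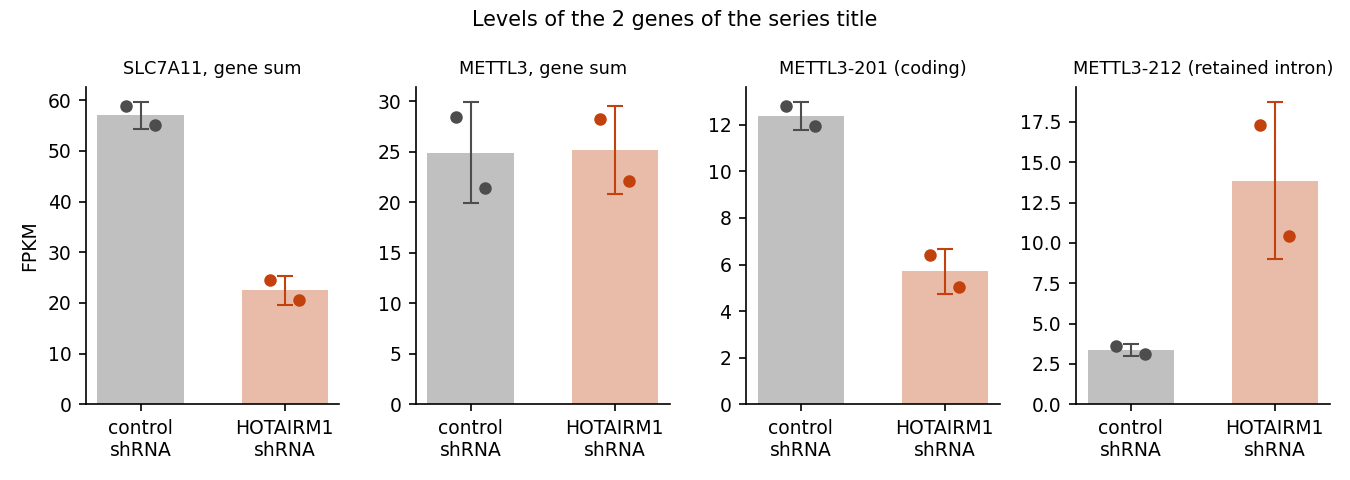
Levels of SLC7A11 and of METTL3 with its transcripts METTL3-201 and METTL3-212, in FPKM on a linear axis, in the 2 control shRNA and 2 HOTAIRM1 shRNA libraries. Each panel has its own axis from 0, points are libraries, bars are group means and error bars are SD (n = 2), and SLC7A11 lies lower in both knockdown libraries while the METTL3 sums overlap.

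The second comparison covered all genes. The largest rises after HOTAIRM1 shRNA included FOSL1, an AP-1 transcription factor subunit, at 94.8 ± 10.1 against 9.27 ± 0.0386 FPKM (log2 fold change 3.28), and TNFAIP3, a feedback inhibitor of NF-kB, at 85.4 ± 0.252 against 10.6 ± 0.825 FPKM (2.95). The largest falls included CLCA2, a membrane protein of stratified epithelia, at 0.919 ± 0.00392 against 12.9 ± 0.788 FPKM (-3.24), DDIT4, an inhibitor of mTORC1, at 28.3 ± 1.71 against 168 ± 0.977 FPKM (-2.55), and TNFSF10, the death ligand TRAIL, at 5.35 ± 0.584 against 35.0 ± 0.950 FPKM (-2.60). Of 10956 genes tested, limma called 1795 at adjusted p under 0.05, 1005 higher and 790 lower in the knockdown libraries. The groups did not overlap for any of the 1795, which the threshold itself all but requires with 2 libraries per group. Nor did they overlap for 66.4% of all genes tested, where chance gives 33.3%. Of the 1795 genes, 408 had a log2 fold change above 1 or below -1, with 201 higher and 207 lower. By the criterion stated for the series, an unadjusted p under 0.05 and a log2 fold change above 1 or below -1, 465 genes passed in the limma fit, 231 higher and 234 lower. With the libraries rescaled to the same FPKM total the called genes split into 880 higher and 880 lower, and with trimmed-mean factors into 876 higher and 892 lower.

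The other named rises were BET1L, a SNARE protein of Golgi transport (log2 fold change 3.80), TAB2, an adaptor of TAK1 (3.12), IL1RL1, the interleukin 33 receptor (3.10), the activin subunit INHBA (2.87), the muscle protein MYPN (2.78), OSBP2 (2.59), the cytokine IL24 (2.54), the chemokine CXCL8 (2.52) and the siderophore-binding protein LCN2 (2.39). The other named falls were the inhibin family subunit INHBE (-3.01), DDX58, the RNA sensor RIG-I (-2.92), the cytokine receptor subunit IL20RB (-2.75), the protocadherin FAT2 (-2.70), the tubulin TUBB2B (-2.56), AMTN (-2.49) and the interferon-induced TRIM22 (-2.48). The limma adjusted p of all these was at most 0.0415. Reads of several leading names cannot be placed with certainty. The readthrough gene ANKHD1-EIF4EBP3 (log2 fold change 4.38) shares 8944 of its 11385 exon bases with ANKHD1 and EIF4EBP3 on its strand and 250 with SRA1 on the other, and UPK3BL1 (-4.53) shares 1318 of its 1342 exon bases with other loci. RPL17-C18orf32, a readthrough whose 1529 exon bases all lie in other genes, was listed at 0 in both knockdown libraries and at 8.81 and 10.1 FPKM in the controls. TAB2 stood at 1.09 ± 0.764 in control and 13.6 ± 7.66 FPKM in knockdown libraries, and over its coding transcripts alone limma adjusted p was 0.296. TUBB2B has near-identical tubulin paralogs, and DDIT4 shares 847 of its 2058 exon bases with the antisense DDIT4-AS1. IL1RL1 had a log2 fold change of 1.79 over coding transcripts alone (limma adjusted p = 0.0587). DDX58 had limma adjusted p = 0.0523 in the test of coding sums. Only coding transcripts of DDX58 were listed, so its values were unchanged there and only the test differed. On a pseudocount of 0.1 the log2 fold changes of INHBE and TUBB2B were -4.55 and -4.51.

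Without any 1 of the 4 libraries limma called 0 genes at adjusted p under 0.05, with a smallest adjusted p of 0.0974 to 0.128 and 2915 to 3416 genes at an unadjusted p under 0.05. With the replicate number as a block limma also called 0 genes (smallest adjusted p 0.0787). Tested per transcript, 6 of 27290 rows passed limma (2 higher and 4 lower, with 4058 at an unadjusted p under 0.05), and sums over protein-coding transcripts alone gave 1064 called genes. Among the called genes named in the Results, not counting those of the closing section, ACO1, ADM, ATF3, CCNE2, CDH1, CHORDC1, CYBRD1, DDX58, IL1RL1, JUNB, LDHA, MT-ND1, MT-ND3, NOTCH1, NRARP, RPL17-C18orf32, SHMT2, SLPI, TAB2, TFRC and WFDC2 lost the limma call over coding transcripts alone, and TUBB2B was not tested there. For ACO1, DDX58, MT-ND1, MT-ND3, NRARP, SLPI and WFDC2, among these, only coding transcripts were listed, so their values were the same in both sums. Their loss came from the test over all genes, whose prior was worth 1.54 instead of 1.94 degrees of freedom. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333.

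**Figure D2:**
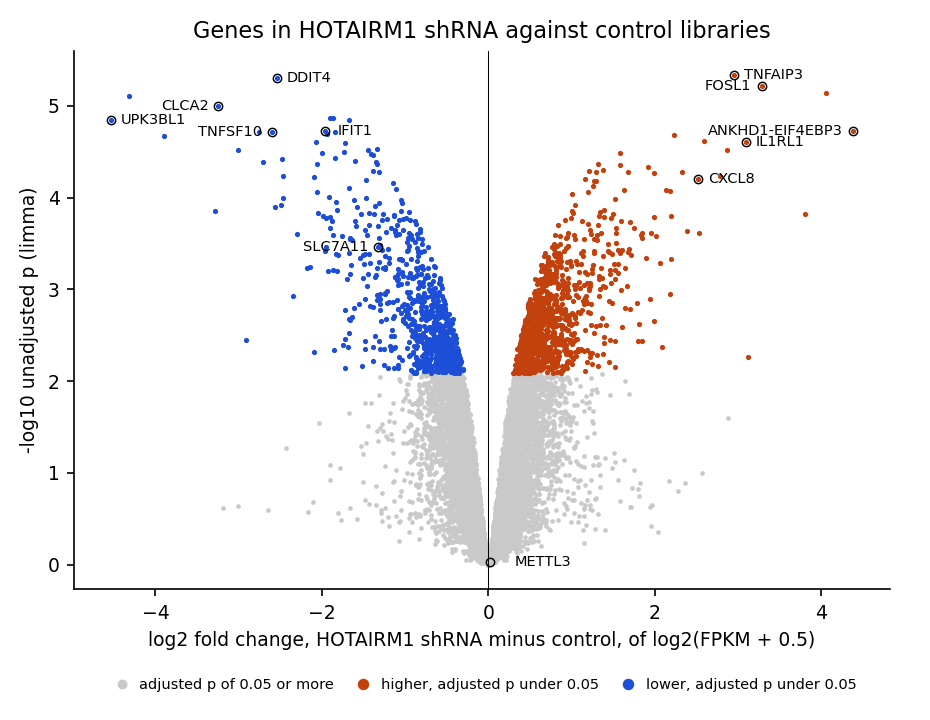
Each point is one of the 10956 genes tested, with its log2 fold change on the log2(FPKM + 0.5) scale, HOTAIRM1 shRNA minus control, on the horizontal axis and minus log10 of limma's unadjusted p on the vertical axis. Coloured points are the 1005 higher and 790 lower genes at adjusted p under 0.05.

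The third comparison took gene lists fixed before the data were examined. The interferon-stimulated genes, which carry the antiviral response, were lower as a group. Of 39 tested, 31 fell and 0 rose (33 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.20 (camera adjusted p = 4.29e-18, adjusted p = 0.354 with an estimated correlation). OASL stood at 71.7 ± 1.25 against 263 ± 12.7 FPKM (-1.87), the translation inhibitor IFIT1 at 41.1 ± 1.17 against 162 ± 11.1 (-1.96), SAMD9 at 32.2 ± 0.893 against 104 ± 0.840 (-1.68), and the antiviral enzyme RSAD2 at 11.6 ± 0.467 against 42.8 ± 0.924 (-1.84). The member higher over the list alone was IRF7, named after its value was seen, at 7.35 against 5.19 FPKM (0.47, limma adjusted p = 0.0600 over all genes). The same libraries also differed in mitochondrially encoded RNA, a sign of RNA quality or composition, which took 4.44% and 3.61% of gene FPKM in control 1 and 2 and 4.69% and 5.21% in knockdown 1 and 2. All 13 mitochondrially encoded genes had a log2 fold change above 0, and 2 were called higher and 0 lower (3 and 0 adjusted over the list alone, median 0.50, with 0.29 to 0.71 over the other settings, camera adjusted p = 0.00458, adjusted p = 0.634 with an estimated correlation). MT-ND1 (0.84) and MT-ND3 (0.80) rose, and MT-ND2 and MT-ATP6 had log2 fold changes of 0.91 and 0.58 with limma adjusted p of 0.0538 and 0.0850.

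Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were lower as a group. Of 35 tested, 20 fell and 1 rose (25 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 9.75e-09, adjusted p = 0.354 with an estimated correlation). Besides DDIT4 they included ASNS, which makes asparagine, at 20.1 ± 1.44 against 78.4 ± 0.671 FPKM (-1.94), the mitochondrial serine enzyme SHMT2 at 17.0 ± 0.820 against 44.6 ± 3.17 (-1.36) and the secreted STC2 at 13.7 ± 0.686 against 30.7 ± 0.709 (-1.13). SLC7A11 is on this list too. Over its coding transcripts alone SHMT2 had a log2 fold change of -0.99 with limma adjusted p = 0.0570. ASNS shares 1985 of its 4455 exon bases with another locus on its strand. The hypoxia response list was also lower, with 8 of 22 tested members called lower and 1 higher (13 and 1 adjusted over the list alone, median -0.67, camera adjusted p = 7.35e-07, adjusted p = 0.354 with an estimated correlation). The mitophagy receptors BNIP3L (-1.48) and BNIP3 (-1.31), the collagen crosslinking enzyme LOX (-1.68) and CA9, a carbonic anhydrase (-2.46, and -4.00 with a pseudocount of 0.1), were its named members. The exceptions, named after their values were seen, were ATF3 among the ATF4 targets (0.52) and ADM among the hypoxia genes (0.83). Of 19 glycolysis genes 6 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 0.00152, adjusted p = 0.547 with an estimated correlation), among them PGK1 at 207 ± 10.2 against 362 ± 2.90 FPKM (-0.81), PGAM1 (-0.58), PFKM (-0.66) and ALDOC (-1.10). Nuclear genes of oxidative phosphorylation had a median of -0.09 (-0.23 to -0.05 over the other settings), with 8 of 48 lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0328, adjusted p = 0.634 with an estimated correlation). ATP5F1A (-0.71, and -1.08 over coding transcripts), COX7B (-0.55) and COX5B (-0.55) fell and ATP5MC3 rose (1.79). The camera call of the oxidative phosphorylation list was lost without control 2 or knockdown 1, and with the replicate number as a block. In these libraries the share of mitochondrially encoded RNA moved the opposite way, as given above.

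Basal and squamous keratinocyte genes were lower as a group, with 10 of 24 tested called lower and 2 higher (13 and 3 adjusted over the list alone, median -0.68, camera adjusted p = 5.74e-05, adjusted p = 0.354 with an estimated correlation). KRT6A, a keratin of activated keratinocytes, stood at 88.8 ± 4.41 against 232 ± 6.85 FPKM (-1.38), KRT14 of the basal layer at 8.06 ± 0.530 against 33.8 ± 1.86 (-2.0), KRT16 at 1.6 ± 0.132 against 7.83 ± 0.903 (-1.98), and the protease inhibitor PI3 at 20.8 ± 0.952 against 79.5 ± 1.54 (-1.91). These keratins have close paralogs and pseudogenes. The members called higher were LCN2 and, named after its value was seen, LAMB3 (0.62). Of 27 epithelial genes 6 were higher and 5 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.670), with CLDN1 (1.34), LSR (0.81) and E-cadherin, CDH1 (0.80), higher and JUP (-0.58) lower. CDH1 had limma adjusted p = 0.251 over its coding transcripts alone. Of 17 mesenchymal genes 3 were higher and 3 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.302), with COL6A2 (1.36) and FBN1 (0.74) higher and FN1 (-1.03) and LOX lower.

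Of 28 immediate early genes, which are transcribed within minutes of stimulation, 16 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.82, camera adjusted p = 3.64e-07, adjusted p = 0.405 with an estimated correlation). With FOSL1 they included EGR1 at 8.32 ± 0.0239 against 1.72 ± 0.0588 FPKM (1.99), the MAP kinase phosphatase DUSP4 at 29.1 ± 0.789 against 9.42 ± 0.387 (1.58) and SPRY2 (1.39). The member that fell was JUNB (-0.63), named after its value was seen. Of 25 NF-kB targets 12 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.62, camera adjusted p = 7.35e-07, adjusted p = 0.354 with an estimated correlation). With TNFAIP3 and CXCL8 they included PTGS2, the prostaglandin synthase COX-2, at 48.7 ± 6.43 against 10.4 ± 0.862 FPKM (2.18), and CXCL3 (2.14). Of 23 YAP/TEAD targets 9 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.000488, adjusted p = 0.405 with an estimated correlation), with the receptor kinase AXL (1.01), IGFBP3 (1.5), CYR61 (0.93) and CTGF (1.40) as examples. Of 9 NOTCH targets 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 0.0328, adjusted p = 0.547 with an estimated correlation), namely CCND1 (0.56), NOTCH1 (0.47), JAG1 (0.44) and NRARP (0.51), of which NOTCH1 and JAG1 encode the receptor and a ligand. The camera call of the NOTCH list was lost without control 1, control 2 or knockdown 2.

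Of 54 G2 and M phase genes 14 rose and 0 fell (20 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 5.27e-05, adjusted p = 0.405 with an estimated correlation). CDC20, the activator of the anaphase-promoting complex, stood at 202 ± 1.42 against 105 ± 6.82 FPKM (0.94), and TUBB4B (0.81), CDCA8 (0.68) and HJURP (0.55) rose. Of 42 S phase genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0896, fry adjusted p = 0.0401), with E2F8 (1.27), RRM2 (0.48), CCNE2 (0.89) and FEN1 (0.39) higher. Of 29 MYC targets 10 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.00122, adjusted p = 0.354 with an estimated correlation). The nucleolar NOP56 stood at 297 ± 2.60 against 121 ± 5.25 FPKM (1.29), and RRS1 (0.86), RRP9 (0.85) and RRP12 (0.69), which serve ribosome assembly, rose. The member that fell, named after its value was seen, was LDHA (-0.64), which the glycolysis list also holds. Of 17 heat shock genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.25, with 0.22 to 0.40 over the other settings, camera adjusted p = 0.0130, adjusted p = 0.405 with an estimated correlation), with CHORDC1 (0.95), HSPA1B (0.49), HSPA1A (0.47) and DNAJA1 (0.44) as examples. HSPA1A and HSPA1B are near-identical copies. The knockdown libraries also had a higher share of mitochondrially encoded RNA.

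**Figure D3:**
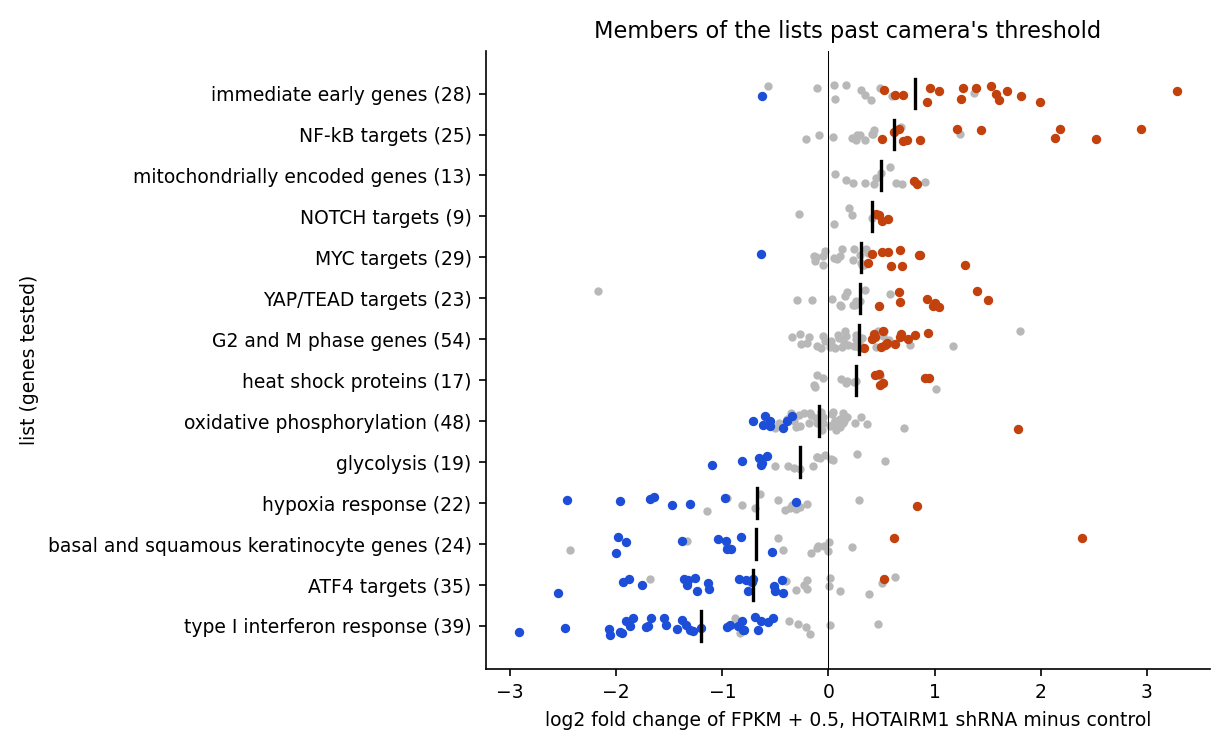
Each point is a tested member of a gene list with camera adjusted p under 0.05, placed by its log2 fold change on the log2(FPKM + 0.5) scale, HOTAIRM1 shRNA minus control. Coloured points passed limma at adjusted p under 0.05 and the black bar is the list's median, which runs from -1.20 for the type I interferon response to 0.82 for immediate early genes.

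Of 39 lists tested, 14 passed camera with a preset correlation, 8 higher and 6 lower. With an estimated correlation between members 0 of the 39 passed (4 at an unadjusted p under 0.05). With fry 16 passed. That test asks whether a list's members are shifted on average, without comparing them with other genes, so a few strong members can carry it. Of the 14 lists, fry did not call the mitochondrially encoded genes (fry adjusted p = 0.189) and oxidative phosphorylation (0.148), and it called 4 others, S phase genes, WNT targets, ferroptosis defence and fatty acid synthesis. Of the ferroptosis defence genes 10 had a log2 fold change above 0 and 14 below, and of the fatty acid synthesis genes 9 and 10. The members of these lists did not share a direction.

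The ferroptosis lists, which bear on the question named in the title, did not pass camera. Of 24 ferroptosis defence genes 2 were higher and 3 lower (3 and 3 adjusted over the list alone, median -0.10, camera adjusted p = 0.470), and fry gave adjusted p = 0.0214. Besides SLC7A11, the fatty acid desaturase SCD fell, at 118 ± 0.761 against 299 ± 3.64 FPKM (-1.34), and the ferritin light chain FTL and the mitochondrial DHODH rose, FTL at 711 ± 85 against 347 ± 13.8 FPKM (1.03) and DHODH at 6.67 ± 0.586 against 3.30 ± 0.268 (0.92). Of 23 ferroptosis promotion genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone, median -0.02, mean 0.04, camera adjusted p = 0.748). PTGS2 and the transferrin receptor TFRC (0.54, limma adjusted p = 0.0540 over coding transcripts alone) were higher, CHAC1, which degrades glutathione, was lower at 1.96 ± 0.305 against 8.54 ± 0.172 FPKM (-1.88), and BACH1 had a log2 fold change of -0.55 with limma adjusted p = 0.0526. CHAC1 and PTGS2 serve as markers of ferroptosis and moved in opposite directions. CHAC1 is also on the ATF4 list, which was lower as a group, and PTGS2 on the NF-kB list, which was higher. Of 19 iron handling genes 5 were higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.470), with HEPHL1 (-2.10) and CYBRD1 (-0.57) lower and ACO1 (0.54) higher. Of 26 targets of NRF2, the regulator of antioxidant genes, 4 were higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.748), with EPHX1 (0.98) and SRXN1 (0.60) higher and AKR1B10 (-2.17) lower. SLC7A11 is on this list as well.

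The m6A lists did not pass camera either. Of 10 m6A writer genes 1 was higher and 0 lower (1 and 1 adjusted over the list alone, median 0.03, camera adjusted p = 0.968). RBM15 rose to 21.7 ± 0.406 from 14.6 ± 0.813 FPKM (0.56), and METTL5, CBLL1 and ZC3H13 had log2 fold changes of -0.31, -0.34 and 0.32 with limma adjusted p of 0.0528, 0.109 and 0.163. Of 16 m6A readers and erasers 2 were higher and 1 lower (2 and 3 adjusted over the list alone, median -0.07, camera adjusted p = 0.641). The reader YTHDF1 rose to 56.9 ± 1.63 from 35.7 ± 1.68 FPKM (0.66), EIF3A rose (0.41), the reader IGF2BP2 fell to 10.5 ± 0.196 from 16.1 ± 0.344 FPKM (-0.59), and YTHDC2 had -0.47 with limma adjusted p = 0.0600. Of 8 HOXA cluster genes, neighbours of HOTAIRM1, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.748). HOXA10 fell to 4.71 ± 1.22 from 13.1 ± 3.18 FPKM (-1.39, limma adjusted p = 0.0438, and -3.685 over its coding transcript alone). HOXA13 and HOXA11 had log2 fold changes of -0.42 and 1.01 with limma adjusted p of 0.121 and 0.332. The HOXA11 value rests largely on control 2, with 6.26 and 1.44 FPKM in control 1 and 2 and 6.42 and 7.17 in knockdown 1 and 2. Exons of these named genes overlap antisense genes.

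Markers of other cell types were mostly low. Of 15 B lymphocyte markers 4 were listed, at most at 0.251 FPKM (FCRLA), and of 20 T and NK lymphocyte markers 2 were listed, at most at 0.326 FPKM (LCK). The highest myeloid marker was CD68 at 12.1 FPKM and the highest endothelial marker ENG at 14.9 FPKM. The highest neural or neuroendocrine marker was ENO2 at 6.21 FPKM. The highest ciliated airway marker was TUBB4B at 639 FPKM, a tubulin that the G2 and M phase list also holds. These 6 lists had fewer than 3 members past the filter and were not tested as lists. TUBB4B was called higher, and of the other members 0 were called over all genes (CD68 and the endothelial EGFL7, named after their values were seen, were higher adjusted over the list alone). Of 5 secretory airway markers 1 was higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.443), with WFDC2 at 1.80, SLPI at -0.45, and MUC1, MUC16 and AGR2 at 0.50, 0.44 and 0.22 with limma adjusted p of 0.119, 0.141 and 0.347.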

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

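Protein-coding sums and tests of single transcripts were chosen after the data were seen, and all other alternatives before. The sum over all transcripts in the main test was not in the plan either, which had assumed values per gene. The 1795 called genes became 1520 to 1799 under other pseudocounts, filters, scalings and variance models (1775 of the 1783 called with a pseudocount of 0.1 were among them). The count was 1064 over protein-coding transcripts (956 shared), 408 with a log2 fold change above 1 or below -1 added, and 3383 at adjusted p under 0.1. With the replicate number as a block limma called 0 genes (3716 at an unadjusted p under 0.05, smallest adjusted p 0.0787) and SLC7A11 lost its call (limma adjusted p = 0.0796, at -1.327, which a block cannot move in this balanced design), and the block changed the call of all 149 called genes other than SLC7A11 that are followed here and of the oxidative phosphorylation list. The deviations of equally numbered libraries correlated at -0.00845 across genes, so no deviation shared by number was seen. This does not settle whether the libraries were prepared in pairs. Leaving out each library gave 0 and 0 as lowest and highest count (2915 to 3416 at an unadjusted p under 0.05), and the fit then rests on 1 residual degree of freedom and assumes that the lone library varies like the other group. Whether the loss of all calls comes from fewer libraries alone was not settled. Simulated data with 1 knockdown library left out cannot answer this, since every changed gene there was changed at least 2-fold. In the real data only 408 of the 1795 called genes had a log2 fold change above 1 or below -1. The cause of the loss on leaving out a library was not tested. SLC7A11 then lay between -1.453 and -1.200 (limma adjusted p 0.0974 to 0.128), and tested as a single transcript it had -1.327 with adjusted p = 0.104. Genes past the study's criterion, 465, became 270 with a filter of 5 FPKM, which tests fewer genes, and 380 to 603 otherwise. The 14 lists became 12 to 17 in other settings, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). Oxidative phosphorylation was also lost without control 2 or knockdown 1, NOTCH targets without control 1, control 2 or knockdown 2, and the other 12 lists passed camera in all 16 settings. With fry 16 lists passed, 12 of the 14 among them, and mitochondrially encoded genes (fry adjusted p = 0.1889) and oxidative phosphorylation (0.1483) were lost. METTL3 turned to -0.01172 at the same FPKM total, -0.01417 with trimmed-mean factors, -0.05474 with quantile normalization, -1.206 over coding transcripts, -1.061 for METTL3-201, -0.01269 for METTL3-206 and -0.1635 for METTL3-205, and without 1 library ran from -0.1827 to 0.2208. Of these 149 called genes, 35 kept their direction and lost the call over coding transcripts (DDX58, SHMT2 and TFRC among them), 14 without a variance trend and 0 to 6 under the other pseudocounts, filters, scalings and robust eBayes. For DDX58 the values were the same in both sums, and only the test changed. Over coding transcripts 2 more lost the call, HERPUD1, which turned to -0.1027, and PSMB10, which turned to -0.003337, and TUBB2B was not tested. Leaving out a library took MT1E from -0.5278 to 0.6036, with -0.1847 without knockdown 2. HOXA11 had 1.91 without control 1 and 0.11 without control 2. Causes of these turns were not tested. No alternatives could be run for HOTAIRM1, and edgeR was not run for want of counts.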

Other observations

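The second list of ATF4 targets and the comparison of transcript shares were tests written before their results were seen, and the tests of scaling, of transcript shares in mixed splits, of the control hairpin, of TOX4 reads, of retained introns in general, of culture conditions and of other splits were chosen after the results were seen. Lists that passed no camera threshold still held called genes. Of 25 p53 targets 4 were higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.497), with GADD45A at 64.6 ± 0.692 against 27.5 ± 0.556 FPKM (log2 fold change 1.22) and PLK3 (1.54, and 2.84 over coding transcripts) higher, and the cell cycle inhibitor CDKN1A at 24.4 ± 0.964 against 53.7 ± 4.02 FPKM (-1.12) and DDB2 (-0.70) lower. Of 21 TGF-beta targets 3 were higher and 5 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.641), with FN1 and TIMP1 (-0.67) among those lower and CTGF among those higher. Of 24 cholesterol synthesis genes 3 were higher and 5 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.470), with INSIG1 (-1.27) and STARD4 (-1.48) lower and FDPS (0.69) and PMVK (0.91) higher. Of 19 fatty acid synthesis genes 2 were higher and 2 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.470, fry adjusted p = 0.0212), with SCD and LPIN1 (-0.79) lower and ELOVL6 (0.73) and GPAM (0.91) higher. Of 31 autophagy and lysosome genes 0 were higher and 4 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.377), namely MAP1LC3B (-0.86), WIPI1 (-1.22), ULK1 (-0.48) and GABARAPL2 (-0.45). Of 32 apoptosis regulators 2 were higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.670), with BMF (-1.91), PMAIP1 (-0.62) and CASP6 (-0.92) lower and the TRAIL receptor TNFRSF10A (0.50) higher.

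Of 38 double-strand break repair genes, which bear on irradiation, 5 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.383), with XRCC3 (0.69), H2AFX (0.73) and RAD52 (0.63) higher and CHEK2 (-0.66) lower. XRCC3 shares 5756 of its 7507 exon bases with KLC1 on the opposite strand, and RAD52 had 0.25 over coding transcripts. Of 21 unfolded protein response genes 2 were higher and 2 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.383), with CRELD2 (0.54) and HERPUD1 (0.69, and -0.10 over coding transcripts) higher and SEL1L (-0.54) and PDIA6 (-0.48) lower. Of 17 class I antigen presentation genes 2 were higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.879), with PSMB10 (0.77, and -0.0033 over coding transcripts) among those higher, PSME1 (-0.72) lower and B2M at -0.36 with limma adjusted p = 0.0518. Of 7 WNT targets 3 were higher and 0 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.203, fry adjusted p = 0.0401), with CCND1, NKD2 (1.39) and DKK1 (1.14) higher and RNF43 at -0.55 with limma adjusted p = 0.0583. Of 10 retinoic acid targets 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.677), with ALDH1A3 (0.96), CRABP2 (1.12) and RARA (0.68) higher and RARRES3 (-0.83) lower. Of 5 metallothionein list members 0 were higher and 2 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.0524), with MT1X (-1.08) and the zinc exporter SLC30A1 (-0.47) lower and MT1F, MT2A and MT1E at -0.83, -0.11 and 0.04. Of 78 cytosolic ribosomal protein genes 0 were higher and 3 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0524), namely RPL22 (-0.48), RPSA (-0.41) and RPLP1 (-0.47), with RPS20 at -0.54 and limma adjusted p = 0.0518. Ribosomal protein and metallothionein genes have many near-identical copies. Among the called genes of these lists, CASP6, CHEK2, GABARAPL2, H2AFX, HERPUD1, MAP1LC3B, NKD2, PSMB10, PSME1, RAD52, RARA, RPL22, RPLP1, SLC30A1, ULK1 and XRCC3 lost the limma call over coding transcripts alone. SLC30A1 had a single listed transcript, a coding one, so its values were the same in both sums and only the test changed. Of 19 replication-dependent histone genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.277). The median had another sign than camera's direction, which was down, in the cholesterol synthesis, TGF-beta, apoptosis, NRF2, HOXA cluster and m6A writer lists, and the mean had another sign than camera's direction in the m6A writer, ferroptosis promotion and class I lists.

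Interferon-stimulated genes were lower in the knockdown libraries. Scaling between libraries was argued against as the cause, since with trimmed-mean factors the list's median log2 fold change was -1.237. A raised interferon response to the control hairpin or its vector could give the same difference, and it stays open because 0 libraries of cells without a hairpin are in the series. An effect of HOTAIRM1 depletion stays open as well and was not tested apart from the hairpin.

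METTL3 values stood lower for the coding transcript and higher for the retained-intron transcript METTL3-212, whose share of METTL3 FPKM was 13.6% in control and 54.15% in knockdown libraries. The quantification may have divided the reads of overlapping models differently, since METTL3-212 shares 1703 of its 1789 exon bases with METTL3-201, and 12.39% of 7798 genes with at least 2 transcripts and a mean of at least 5 FPKM showed as large a gap between the 2 single control libraries. That share was past the 5% set beforehand for single libraries, so the prediction written for this explanation was met. The METTL3 gap itself lay between means of 2 libraries. Between such means, a comparison chosen after the results were seen, 5.23% of these genes showed such a gap between the groups. In the splits that mix the groups 4.26% and 4.67% did, which is under that 5%. The comparisons differ, so this explanation stays open. Reads of TOX4 are another candidate source for METTL3-212, with 337 of its bases in TOX4 exons. Since METTL3-212 shares 1703 of its 1789 exon bases with METTL3-201, most of those 337 bases lie in METTL3-201 too. TOX4 reads could thus fall on either transcript and do not by themselves account for the lower coding transcript. A change in METTL3 splicing after HOTAIRM1 depletion stays open and untested. More retained introns in general cannot be told apart from replicate spread, since the share of FPKM in retained-intron transcripts was higher by 0.1847 percentage points, with 8.37% and 7.92% in the controls and 8.73% and 7.92% in the knockdown libraries.

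SLC7A11 was lower together with ATF4 targets. Lower ATF4-dependent transcription is a candidate explanation, and in a second list of 24 ATF4 targets, which shares no gene with the first, the median log2 fold change was -0.2968 (6 lower and 1 higher, camera p = 0.000143, p = 0.0678 with an estimated correlation), just short of the bound of -0.3 set for it, so this stays open. Culture density or medium at harvest could lower ATF4, hypoxia and glycolysis genes together, and the hypoxia list had a median of -0.6709, which the design cannot part from the hairpin. RNA stability, the mechanism the series title names, cannot be read from FPKM and was not tested.

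The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split, the only 1 of the 3 with as many calls, gave 1795 called genes and the highest of the others 0 (148 and 157 genes at an unadjusted p under 0.05). Each of the others puts 1 control and 1 knockdown library on either side. Any difference between the groups then adds to the spread within each side, so few calls were likely there in any case. No conclusion is drawn from the contrast.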
